A study of Mus musculus with 12 samples.

How the data were processed

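The libraries were made from E14 mouse embryonic stem cells, a line of 129/Ola background, grown without feeders either in serum with LIF, called primed by the submitters, or in 2i, called naive. The 2i medium held N2, B27 and LIF with the MEK inhibitor PD0325901 and the GSK3 inhibitor CHIR99021. Cells received a lentiviral shRNA against Setdb1, which encodes an H3K9 methyltransferase, or a scrambled shRNA (shScr), were selected with puromycin and were collected after 3 days of selection, per the labels' protocols. RNA was depleted of ribosomal RNA and made into strand-specific libraries, per the same protocols. These place the word either before a single named RNA extraction kit, so the use of another kit for some libraries stays open. Each of the 4 groups, serum control, serum knockdown, 2i control and 2i knockdown, held 3 libraries numbered 1 to 3. No group held a rescue of Setdb1 or was labelled with another shRNA against it. Effects of Setdb1 depletion therefore cannot be told apart from other effects of the shRNA, in either medium or in what the media share. The labels do not state whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

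Both deposited tables hold log2-scale variance-stabilised values made by the authors, 1 table of 26061 genes and 1 of 1217 repeat families, each with 1 column per library. The submitters' processing notes name Trim Galore 0.3.3, TopHat2 2.0.9, DESeq2 without a version and the genome build mm9. The counting tool, the gene and repeat annotation, the treatment of reads that map to several places and the use of strand in counting are not given in the sources used here. Near-identical gene copies, repeat families of similar sequence, overlapping genes and antisense genes are therefore uncertain. No coordinates are given because the reference at hand was of another build than mm9.

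The transformation was inverted for each table by solving for its parameters, and 100% of values came out as whole reads within 0.01 of a read, with a largest distance of 0.00032 for genes and 0.00478 for repeat families. Recovered reads gave the depth: 4821181 to 15509401 gene reads and 4407665 to 8962913 repeat reads per library. Normalised reads are the recovered reads divided by the size factor of the library, and each table has its own size factors. The tables were tested separately, and shares set across them use raw reads. Tests used the deposited values as they are. A log2 change on this scale understates the change of features with few reads, so folds were computed from mean normalised reads. Where a control group had no read, the fold is a lower bound against 3 reads over the group, and where it had 1 to 3 reads no fold is given. Such bounds and all read totals cover counting error only.

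Features were tested with limma 3.58.1 in R 4.3.3. The model had 1 mean per group over all 12 libraries, 8 residual degrees of freedom and empirical Bayes variances with a mean-variance trend. A feature was kept when its mean lay at least 0.5 above the lowest value of its table, which was 4.4522 for genes and 3.5352 for repeat families. This left 14487 genes and 1097 repeat families. Tests were two-sided, except that Fisher's exact tests of overlaps and of name families looked for an excess only. A feature passed at a Benjamini-Hochberg adjusted p under 0.05 within a table and a comparison. The 4 comparisons were knockdown against control in serum, knockdown against control in 2i, the difference of these 2 changes (2i minus serum), and 2i against serum in control cells. The design, the lists, the rule for named features and the first set of alternatives were fixed before the data were examined.

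The 22 gene lists covered germline, 2-cell-stage, trophoblast, naive pluripotency, general pluripotency, primed and early post-implantation, endoderm, mesoderm, neural, imprinted, retroelement silencing and H3K9 methylation, DNA methylation and hydroxymethylation, interferon response and double-stranded RNA sensing, p53 target, MEK-ERK response, Wnt response, fibroblast, cytosolic ribosomal protein, mitochondrially encoded, stress and unfolded protein response, cholesterol synthesis and replication-dependent histone genes. Members listed in the tables under an older symbol were matched through the gene names of the GRCm38 assembly, such as Gm1564 for Meioc. The 11 repeat lists were defined by family names. Lists of at least 5 kept members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a table and comparison. Camera with an estimated correlation and fry, which tests whether the members move one way on balance, were run beside it. Some genes stand in more than 1 list.

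Named features followed a rule. It took Setdb1 and the 10 largest rises and 10 largest falls among genes that passed with all 3 libraries of one group beyond those of the other. It also took the 8 largest rises and 4 largest falls of repeat families, and up to 4 passing members of each list, or the 2 largest changes where none passed. Predicted gene models were left out of the largest changes.

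Replicate numbers were checked for pairing by the correlation of deviations from the group means. In serum the genes of same-numbered libraries deviated together, with correlations of 0.58, 0.23 and 0.51. Values with the replicate number as a block therefore stand beside the serum results. In 2i the correlations were 0.46, 0.06 and 0.52, so replicate 2 did not pair, and blocked values for 2i are given with the alternatives. No chi-square comparison of same-group libraries lay within sampling noise, with values per feature of at least 43.65 for genes and 330.03 for repeat families, so all 12 libraries were counted.

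The first set of alternatives changed the filter, the libraries in the fit, the scaling, the variance model, a minimum change and the replicate block, and left out each library in turn. Added after the data were examined were voom on the recovered reads, array weights, size factors of the gene table for repeats, scaling of repeats without structural RNA, the share of structural RNA as a covariate, and fits without libraries numbered 3. The tests were run on simulated data made from the real means and depths, with 200 genes or 50 repeat families changed by known folds. At 4-fold they recovered 46.3% of changed genes in serum, 32.8% in 2i and 13.4% for the difference of changes, and 88.2%, 94.1% and 64.7% of repeat families. False calls made up 3.1, 6.3, 7.9 and 10.4% of gene calls in the 4 comparisons in order, and 9.5, 8.6, 0 and 0% of repeat calls. Some shares thus lay above the 5% aimed at. Each came from a single simulated data set with at most 11 wrong calls, too few to tell the rate from 5%. Simulated changes left out the features of lowest expression, and noise was independent between features, unlike shifts of composition shared by many features. Summaries used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.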

Results

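Ribosomal-RNA-depleted, strand-specific RNA sequencing was done on E14 mouse embryonic stem cells in serum or 2i medium, each with a scrambled shRNA or an shRNA against Setdb1, with 3 libraries in each of the 4 groups. SETDB1 places H3K9 methylation and is known as a repressor of endogenous retroviruses in these cells. Replicates 1 to 3 held 10510955, 13013715 and 9900012 gene reads in the serum control and 15033758, 13028732 and 11559278 in the serum knockdown. They held 15509401, 14541353 and 9903046 in the 2i control and 13838706, 11360663 and 4821181 in the 2i knockdown. Repeat reads ranged from 4407665 to 8962913 per library. Structural RNA and tRNA repeats, which include the small nuclear RNAs and 7SK, took 24.2, 29.9 and 48.3% of repeat reads in the serum control and 16.2, 15.6 and 42.5% in the serum knockdown. Their shares were 32.1, 38.9 and 64.6% in the 2i control and 19.9, 55.5 and 69.5% in the 2i knockdown, so libraries of the same group differed in composition. The 13 mitochondrially encoded genes in the table had 0 reads in all 12 libraries. The first principal component of the gene table held 38.6% of its variance and the second 17.6%.

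Setdb1 itself was lower in every knockdown library than in every control library of the same medium. In serum its normalised reads were 2959, 2237 and 1587 in the controls and 418, 379 and 409 after knockdown, a log2 change of −2.33 (SE 0.33, limma adjusted p = 0.00219). In 2i they were 3607, 2724 and 2253 in the controls and 837, 610 and 340 after knockdown, a change of −2.24 (SE 0.33, limma adjusted p = 0.00173). The difference of the changes was 0.09 (SE 0.47, limma adjusted p = 1.00), and Setdb1 differed by 0.35 (SE 0.33, adjusted p = 0.656) between the control groups.

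**Figure D1:**
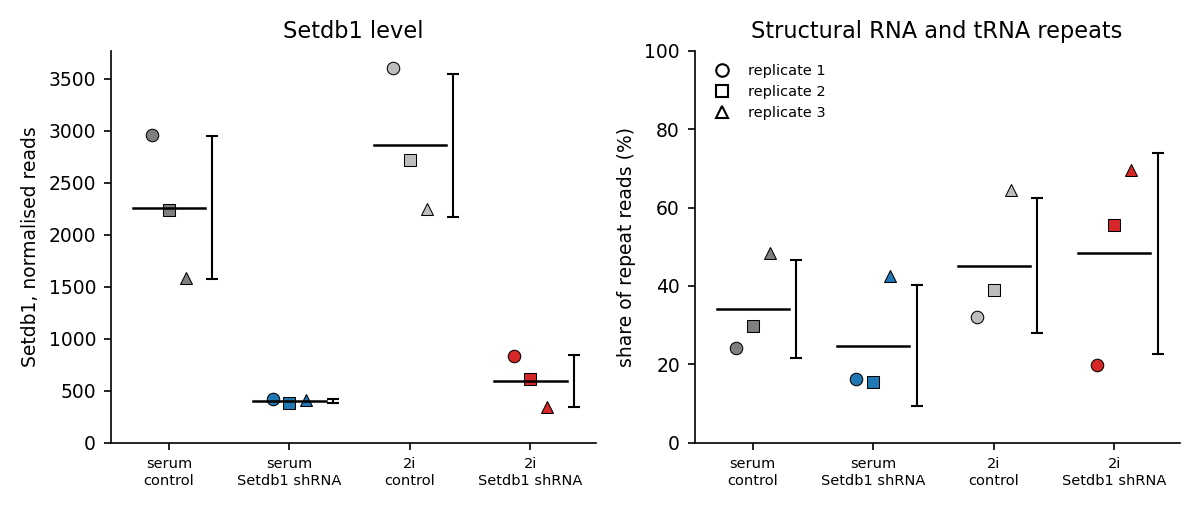
Setdb1 normalised reads (left) and the share of structural RNA and tRNA repeats among repeat reads in percent (right) for each of the 12 libraries, with a marker shape for each replicate number, a line at the group mean and an error bar of 1 SD. The 6 knockdown libraries sit at 340 to 837 Setdb1 reads and the 6 control libraries at 1587 to 3607, while the share on the right spans 15.6 to 69.5%.

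The first comparison asked which genes changed with the shRNA against Setdb1 in serum. Clec2i, a C-type lectin-like ligand of natural killer cell receptors, had no read in the controls and 1213 ± 169 normalised reads after knockdown (SD, n = 3), at least 1206-fold higher. Mmp12, the macrophage elastase, went from 0 to 736 ± 407 reads, at least 732-fold higher, and the collagenase Mmp1b from 0 to 201 ± 26.9, at least 199-fold higher. The serine protease inhibitor Serpina3m rose 519-fold to 923 ± 234 reads, the cytochrome P450 Cyp2b23 106-fold to 1186 ± 424, the aldo-keto reductase Akr1c21 113-fold and the metalloprotease Mep1b 20.8-fold. Rbmy1a1, a Y-linked RNA-binding protein of the testis, had 1 control read and 1127 ± 591 reads after knockdown (log2 change 5.47), and the secreted protein Cthrc1 had 3 control reads and 536 ± 222 (log2 change 4.40). The nucleotide pyrophosphatase Enpp3 rose by 3.60. Control reads were few, and without control replicate 2 Serpina3m and Akr1c21 had none and the folds of Cyp2b23 and Mep1b became 732 and 33.7. Without control replicate 1 or 3 that of Serpina3m became 346.

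Of the 36 germline genes tested in serum, 2 rose, and 11 rose when adjusted over the list alone. The 2 were Stk31, a kinase of male germ cells, at 363 ± 79.9 to 3665 ± 1482 reads (10.1-fold), and Tex15, needed in meiosis, at 636 ± 151 to 5429 ± 2959 reads (8.54-fold). The list median was 0.96 (camera adjusted p = 6.82e-13), and its adjusted p = 0.2997 with an estimated correlation. Naive pluripotency genes had a median of −0.72 with 0 of 20 passing (camera adjusted p = 1.98e-07). This was the only gene list call in serum that held, with an adjusted p = 0.0499 with an estimated correlation, while fry gave an adjusted p = 0.0641. The orphan receptor Nr0b1 changed by −1.23 (adjusted p = 0.524), and Dppa3, a naive gene and maternal factor, by 3.15 (adjusted p = 0.194), the 1 list member that rose when adjusted over the list alone. Primed and early post-implantation genes had a median of 0.91 with 0 of 18 passing (camera adjusted p = 0.00613, adjusted p = 0.970 with an estimated correlation). Among them stood Otx2, a transcription factor of that stage, at 1.31 (adjusted p = 1.00) and Wnt8a at 1.58 (adjusted p = 0.407). Replication-dependent histone genes had a median of −0.53 with 0 of 32 passing (camera adjusted p = 2.56e-06, adjusted p = 0.971 with an estimated correlation). The histone list was also higher by 0.95 in the 2i libraries rich in structural RNA, and each serum knockdown library held a smaller share of structural RNA than the control library of the same number.

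Among imprinted genes 1 of 38 rose in serum, the paternally expressed Usp29 (2.38, 10.5-fold, 16.8-fold without control replicate 3). Among cholesterol synthesis genes 1 of 23 rose, the isomerase Idi1 (1.78, 802 ± 31.6 to 2897 ± 599 reads). These lists had medians of 0.11 and 0.06 and the same count when adjusted over the list alone. No member passed in the 15 other tested gene lists, whose camera adjusted p ranged from 0.611 to 0.941 together with these 2 lists. Their medians were 0.11 for 2-cell-stage, −0.24 for trophoblast, −0.07 for general pluripotency, −0.10 for endoderm, 0.12 for mesoderm, −0.04 for neural and 0.09 for retroelement silencing genes. They were 0.09 for DNA methylation, 0.08 for interferon response, 0.08 for p53 target, −0.11 for Wnt response, 0.29 for fibroblast, −0.09 for ribosomal protein and 0.10 for stress response genes. The MEK-ERK response list had a median of −0.03 and a mean of 0.04, and camera placed the DNA methylation list below other genes against the sign of its median. Apart from Setdb1, falls were few and included the Ras-family GTPase Mras (−2.07), the dihydropyrimidinase Dpys (−2.11), the membrane protein Emp1 (−2.10), Tmem64 (−1.63) and the auxilin Dnajc6 (−1.56).

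In all, 94 of 14487 genes passed in serum with limma, 87 higher and 7 lower. The libraries of both groups did not overlap for 9.7% of the genes tested, where chance gives 10%. Here and below, that 10% assumes exchangeable libraries and no ties. Same-numbered serum libraries deviated together, so the 10% is a rough guide only. With the replicate number as a block 171 genes passed, 149 higher and 22 lower, and with the block within medium 211 passed, 177 higher and 34 lower. Dppa3 passed in both blocked fits (adjusted p = 0.00379 and 0.000117), and Nr0b1 (adjusted p = 0.0473) and Otx2 (adjusted p = 0.0288) in the latter alone. Without 1 library at a time the count was 37 without control replicate 1, 58 without control replicate 3, 43 without knockdown replicate 2 and 60 without knockdown replicate 3. Dpys, Emp1 and Mcf2 (−1.18) lost their call in all 6 fits without 1 library. Mras and Usp29 lost it in 5, Dnajc6 in 4, Tmem64 in 3, Enpp3 in 2 and Idi1 in 1, while the 12 other named genes kept it. With voom Dnajc6, Dpys and Usp29 were among the named genes that did not pass.

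The repeat families that rose in serum came mostly from the class I and class II endogenous retroviruses. MMERGLN-int, the internal part of a class I gammaretrovirus-like element, rose 67.7-fold, from 1314 ± 19.2 to 88960 ± 63930 reads (log2 change 5.79, SE 0.47, limma adjusted p = 1.47e-06), and 40.9-fold without knockdown replicate 2. MMERVK10C-int rose 11.2-fold from 4221 ± 351 to 47230 ± 17730 reads, and the long terminal repeat RLTR1B rose 10.03-fold. The intracisternal A particle (IAP) internal part IAPEz-int rose 3.75-fold, from 13390 ± 843 to 50230 ± 19700 reads. LTR45C had 1 control read and 142 ± 101 reads after knockdown.

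All 7 families that passed in the MMERVK10C list of 9 rose, with a median of 2.32, among them RLTR10C (2.91), RLTR10B2 (2.84) and RLTR10B (2.34). In the IAP list 8 of 16 rose, with a median of 1.37, among them IAPLTR3-int (2.18), IAPLTR4_I (2.08) and IAP-d-int (1.73). Adjusted over the list alone, 9 and 16 families rose, and both calls held, each with an adjusted p = 0.0027 with an estimated correlation. Of 24 class I families 6 rose (13 adjusted over the list alone), with a median of 0.89, including RLTR1B-int (2.65) and MuRRS4-int (1.28). Of 91 other class II families 12 rose (18 adjusted over the list alone), with a median of 0.30, including RLTR44B (2.75), RLTR44-int (2.42), RLTR44A (2.21) and RLTR44D (1.85). These medians stayed positive under every scaling tried. Camera gave adjusted p values of 1.26e-14 and 1.37e-13 for the class I and other class II lists, with an adjusted p = 0.0735 and 0.219 with an estimated correlation.

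The ETn and MusD list had a median of 1.04 with 0 of 5 passing and 1 when adjusted over the list alone (camera adjusted p = 0.00165, adjusted p = 0.314 with an estimated correlation). ETnERV2-int stood at 1.31 (adjusted p = 0.152). MERVL and MT2 families, transcribed at the 2-cell stage, had a median of −0.29 with 0 of 7 passing (camera adjusted p = 0.0954). MERVL-int stood at −0.61 (SE 0.66, adjusted p = 0.924). MaLR families had a median of −0.10 with 0 of 103 passing (camera adjusted p = 0.00646, adjusted p = 0.589 with an estimated correlation). SINEs had a median of −0.17 with 0 of 22 passing (camera adjusted p = 0.00646, adjusted p = 0.462 with an estimated correlation). Mouse L1 families had a median of 0.16 with 0 of 16 passing (camera adjusted p = 0.365), and the 4 satellite families, too few to test, of 0.32. Structural RNA and tRNA repeats had a median of −0.44 with 1 of 76 passing, tRNA-Lys-AAA at −1.49 (camera adjusted p = 4.82e-06, adjusted p = 0.377 with an estimated correlation). Their share of repeat reads in these libraries ran from 15.6 to 48.3%. In all, 37 of 1097 families passed with limma, 36 higher and 1 lower, and the groups did not overlap for 14.6% of families, where chance gives 10%. With the replicate number as a block 63 passed, 61 higher and 2 lower, and with the block within medium 72, 68 higher and 4 lower, ETnERV2-int in both (adjusted p = 0.00155 and 0.00031). Of the 18 named families that passed, 13 kept their call without any 1 library, and RLTR44D and tRNA-Lys-AAA did not pass with voom.

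The second comparison asked the same in 2i. Mmp12 rose 906-fold, from 2.12 ± 1.89 to 1923 ± 1203 reads (SD, n = 3), Serpina3m 719-fold and Rbmy1a1 400-fold, and Clec2i went from 0 to 685 ± 504 reads, at least 841-fold higher. The aldo-keto reductase Akr1c13 rose 121-fold and Akd1, which holds adenylate kinase domains, 201-fold. Tex101, a germ cell surface protein, rose 839-fold from 1.31 ± 1.38 to 1100 ± 1383 reads. Akr1c21 (log2 change 4.67) and the kininogen Kng2 (4.45) each had 3 control reads, and Asb13, which holds ankyrin repeats, rose 56.1-fold. Without knockdown replicate 3 the folds of Tex101, Mmp12 and Akr1c13 fell to 230, 587 and 73.0, and without control replicate 3 that of Akr1c13 was 80.6. Higher folds came without control replicate 1 for Mmp12 (1390) and without control replicate 3 for Rbmy1a1 (1630). Without control replicate 2 they were 1870 for Tex101, 1400 for Serpina3m, 341 for Akr1c13, 316 for Akd1 and 91.1 for Asb13.

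Germline genes in 2i had 5 of 36 higher, 14 when adjusted over the list alone, and a median of 1.02 (camera adjusted p = 1.13e-15, adjusted p = 0.390 with an estimated correlation). Stk31 rose 13.9-fold from 364 ± 53.9 to 5038 ± 2026 reads, the piRNA pathway gene Mael 18.2-fold, and the testis bromodomain gene Brdt 11.6-fold. The others were Tex101 and Sycp2, a part of the synaptonemal complex (1.86), the latter named after its values were seen. Genes of the 2-cell stage had 2 of 25 higher, 15 when adjusted over the list alone, and a median of 1.75 (camera adjusted p = 5.75e-15, adjusted p = 0.443 with an estimated correlation). The 2 were Gm5662, from 76.5 ± 54.0 to 1784 ± 1233 reads (limma adjusted p = 0.0158), and the deubiquitinase gene Dub1a, from 4.72 ± 4.18 to 186 ± 117 (limma adjusted p = 0.0136). Both have near-identical copies, so their reads are uncertain. The fold of Gm5662 was 23.3 with all libraries, 15.4 without knockdown replicate 1 and 38.3 without control replicate 1, and that of Dub1a was 39.5 and became 60 without control replicate 1.

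Interferon response genes in 2i had 3 of 27 higher, with 4 higher and 1 lower when adjusted over the list alone, and a median of 0.37 (camera adjusted p = 0.00162, adjusted p = 0.411 with an estimated correlation). Rtp4 went from 0 to 105 ± 103 reads, at least 130-fold higher, and the antiviral GTPase Mx2 from 0 to 36.2 ± 36.6, at least 44.4-fold higher. Bst2, which tethers viruses to the cell surface, rose 11.9-fold, or 6.24-fold without knockdown replicate 3. After centring 2 members passed and after quantile normalisation 1. Ribosomal protein genes had a median of 0.51 with 0 of 49 passing (camera adjusted p = 7.78e-05, adjusted p = 0.852 with an estimated correlation). Between the 3 libraries of 2i with 55.5 to 69.5% structural RNA and the 3 with 19.9 to 38.9%, that list differed by a median of 1.32, the histone list by 0.95 and the germline list by 0.89, while the MEK-ERK response, Wnt response and DNA methylation lists differed by −0.72, −0.57 and −0.52. Of the 3 former libraries 2 were of the knockdown. Cholesterol synthesis genes had a median of −0.41 with 0 of 23 passing (camera adjusted p = 0.00306, adjusted p = 0.637 with an estimated correlation), and Idi1 stood at 0.75 (adjusted p = 0.473).

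In the Wnt response, retroelement silencing and fibroblast lists 1 gene each rose. They were the Wnt inhibitor Apcdd1 (1.73, adjusted p = 0.0446), Atf7ip2, a relative of a SETDB1 partner (1.36, adjusted p = 0.0453), and the collagen-binding proteoglycan Lum, with 4 control reads and 460 ± 325 reads after knockdown (4.03). Those lists had medians of −0.44, −0.12 and 0.37 (camera adjusted p = 0.0797, 0.608 and 0.0661). Adjusted over the list alone the Wnt list had 1 higher and 2 lower and the others 1 higher each. No member passed in the naive pluripotency list (median −0.26, camera adjusted p = 0.0662), where Klf4 stood at −1.10 (adjusted p = 0.310) and Dppa3 at 2.89 (adjusted p = 0.185). Nor did any in the trophoblast, general pluripotency, primed, endoderm, mesoderm, neural, imprinted, DNA methylation, p53 target, MEK-ERK response, histone and stress response lists, whose medians lay between −0.37 and 0.22 and whose camera adjusted p lay between 0.117 and 0.750. The means of the neural and DNA methylation lists had the opposite sign of their medians. Adjusted over the list alone 1 primed and 1 mesoderm gene were lower, 1 p53 target was higher, and 1 MEK-ERK response gene was higher and 1 lower. Falls included Nkx1-2, a homeobox gene (469 ± 158 to 46.5 ± 57.0 reads, log2 change −2.82), the neuropilin Nrp2 (−2.07) and the hexosamine pathway enzyme Gfpt2 (−1.78). Others were the somatostatin receptor Sstr2 (−1.71), the keratin Krt42 (−1.60), the natriuretic peptide receptor Npr3 (−1.51) and the neurotrophin receptor Ngfr (−1.48).

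In all, 184 genes passed in 2i with limma, 176 higher and 8 lower, and the groups did not overlap for 10.7% of genes, where chance gives 10%. Without 1 library at a time the count was 99 without control replicate 1, 111 without control replicate 2 and 104 without knockdown replicate 3. It was 68 without both libraries numbered 3, an omission chosen after the data were examined. In such fits without 1 library 19 of the 30 named genes kept their call, and Apcdd1, Atf7ip2, Brdt, Bst2, Dub1a, Gm5662, Krt42, Mx2, Ngfr, Npr3 and Sstr2 did not. With voom Apcdd1, Atf7ip2, Brdt, Bst2, Dub1a, Gm5662, Krt42, Mael, Ngfr, Npr3, Sstr2 and Tex101 did not pass.

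The median change of all repeat families in 2i was 0.24, and list medians are given also relative to it. IAPEz-int rose 17.1-fold, from 11220 ± 3152 to 191500 ± 20820 reads (log2 change 4.12, 3.88 relative to the shift, SE 0.31, limma adjusted p = 2.62e-07), IAPLTR1_Mm 14.2-fold and IAPEy-int 17.5-fold. MMERGLN-int rose 30.3-fold to 45510 ± 28670 reads, RLTR1B 11.1-fold and MMERVK10C-int 9.57-fold. Without knockdown replicate 1 the folds of MMERVK10C-int and MMERGLN-int were 4.31 and 19.3, and without knockdown replicate 2 that of IAPEy-int was 8.79.

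The IAP list had 15 of 16 families higher and a median of 2.58, or 2.34 relative to the shift, with IAPLTR3-int at 3.17, IAPLTR2_Mm at 2.99 and IAPLTR2a at 2.88. All 9 MMERVK10C families were higher, with a median of 2.12, or 1.88 relative to the shift. Both calls held, with an adjusted p = 0.0032 and 0.0249 with an estimated correlation, and adjusted over the list alone 16 and 9 families rose. Of 24 class I families 15 rose (18 adjusted over the list alone; median 1.41, relative 1.17), such as MuLV-int (2.43) and MMVL30-int (2.00). The fold of MMVL30-int was 4.59 with all libraries, 2.46 without knockdown replicate 3 and 7.04 without control replicate 3. That of MuLV-int was 7.16, and 10.8 without control replicate 2. Of 91 other class II families 36 rose (49 adjusted over the list alone; median 0.76, relative 0.53), such as RLTR45-int (2.01) and RLTR9B2 (1.95). Camera gave adjusted p values of 1.39e-12 and 1.57e-15, with an adjusted p = 0.104 and 0.168 with an estimated correlation. These 4 medians stayed positive under every scaling tried.

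MERVL and MT2 had 2 of 7 families higher in 2i, 3 when adjusted over the list alone, with a median of 0.37, relative 0.14, which became −0.14 with quantile normalisation (camera adjusted p = 0.148). MERVL-int rose 8.19-fold from 4705 ± 2216 to 38550 ± 43870 reads (log2 change 2.44, 2.20 relative to the shift, SE 0.66, limma adjusted p = 0.0271). Without knockdown replicate 1, which held 88700 reads against 7284 and 19650, the fold was 2.86 and the log2 change 1.48 (adjusted p = 0.084). The call was also lost without control replicate 2 or 3. It was also lost after centring (2.09, SE 0.66, adjusted p = 0.0748) and with quantile normalisation (1.85, SE 0.69, adjusted p = 0.095). ETn and MusD had 2 of 5 higher (2 adjusted over the list alone; median 0.73, relative 0.49, camera adjusted p = 0.141), ETnERV3-int (2.58) and ETnERV2-int (1.41). The fold of ETnERV3-int was 6.71 with all libraries, 2.77 without knockdown replicate 1 and 13.4 without control replicate 1. Mouse L1 had 1 of 16 higher, L1_Mur2 at 0.91, and 10 when adjusted over the list alone (median 0.93, relative 0.69, camera adjusted p = 0.00182, adjusted p = 0.441 with an estimated correlation). MaLR families had 7 of 103 higher and 5 when adjusted over the list alone. Among them were ORR1A1-int (1.79, 4.11-fold, or 2.45-fold without knockdown replicate 1) and ORR1A0 (1.46). The MaLR median was 0.32, relative 0.09, and was −0.03 after centring and −0.10 with quantile normalisation (camera adjusted p = 0.205). Structural RNA and tRNA repeats had 2 of 76 higher, 4.5SRNA at 1.48 and tRNA-Leu-CTG at 1.54, and 0 when adjusted over the list alone (median 0.38, relative 0.15, camera adjusted p = 0.980). SINEs had 0 of 22 passing, a median of 0.10, relative −0.14, and a camera direction opposite to its sign (adjusted p = 0.205). The satellite median was 0.54.

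In all, 115 of 1097 families passed in 2i with limma, 114 higher and 1 lower, LTR50 at −0.88, and the groups did not overlap for 23.8% of families, where chance gives 10%. The split was 67 higher and 25 lower after centring, 74 and 82 with quantile normalisation and 87 and 25 when scaled without structural RNA. The count was 71 without control replicate 1, and 19 of the 30 named families kept their call without any 1 library. With voom LTR50 and RLTR44D did not pass.

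**Figure D2:**
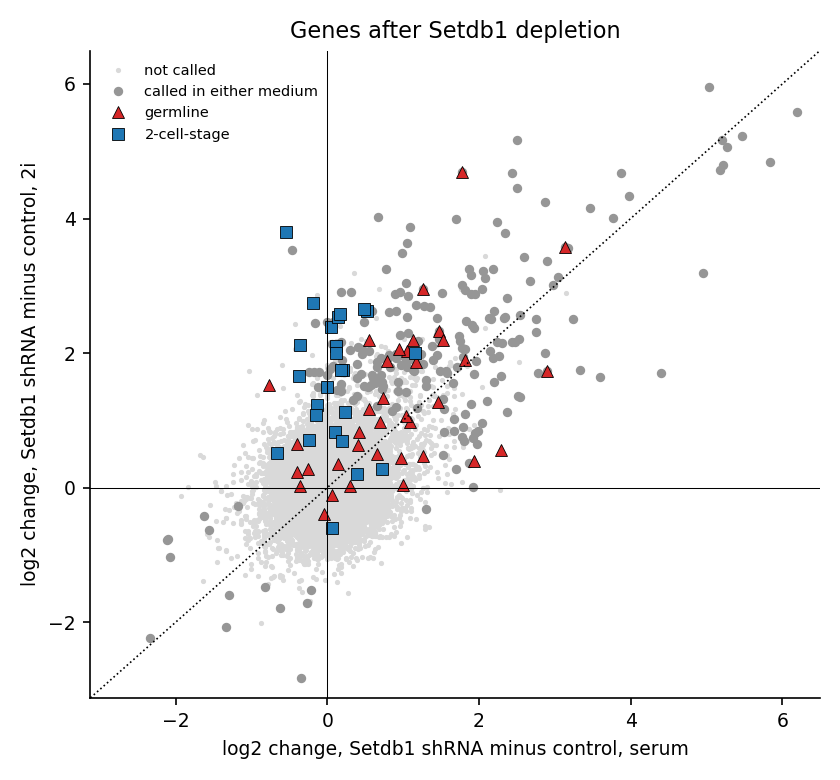
Log2 change of each tested gene after Setdb1 knockdown in serum (horizontal) and in 2i (vertical), with genes called in either medium and members of chosen lists marked and a dotted line where both changes are equal. Of the genes called higher, 87 in serum and 176 in 2i, 59 are shared.

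Most genes that rose in serum also rose in 2i. The 59 genes called higher in both, of 87 and 176, compare with 1.06 for independent lists (Fisher's exact test for an excess, p = 7.10e-96). Stk31, Mmp12, Clec2i, Serpina3m, Rbmy1a1 and Akr1c21 were among them. The knockdowns share no library, but both were tested with the same estimated spread of each feature, and features are not independent. The p-values of the overlaps are therefore descriptions only. Setdb1 was the 1 gene lower in both. Of the 87 genes higher in serum 86 had a positive change in 2i, and of the 176 higher in 2i 167 had one in serum. Of repeat families 35 were higher in both, against 3.74 for independent lists (Fisher's exact test for an excess, p = 6.43e-36), and 0 were lower in both. Across called features, which are not independent replicates, the changes correlated with r = 0.65 for 218 genes and 0.71 for 117 families. Without serum control replicate 1 or serum knockdown replicate 2 the genes called in both numbered 30 and 38, against 60 with all libraries. For these omissions the 2i calls were those of the fit with all libraries. The blocked fits gave 98 and 121.

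The third comparison tested whether the response differed between the media. IAPLTR1_Mm and IAPEz-int rose more in 2i than in serum, by 2.38 (SE 0.38, limma adjusted p = 0.011) and 2.28 (SE 0.44, limma adjusted p = 0.0488), against a median difference of all families of 0.31. Relative to that shift the differences were 2.07 and 1.97. The IAP list had a median difference of 1.11, or 0.80 relative to the shift, with 2 of 16 families passing and 6 when adjusted over the list alone. Camera gave an adjusted p = 6.86e-07 and an adjusted p = 0.109 with an estimated correlation, and the median stayed positive under every scaling. The MMERVK10C list had a median difference of −0.03 with 0 of 9 passing (camera adjusted p = 0.230), which became 0.44 with the size factors of the gene table. ETn and MusD had a median difference of −0.27 and a mean of 0.11 with 0 of 5 passing, and the median became 0.27 with those factors. MERVL-int stood at 3.05 without passing.

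Of 1097 families 2 passed for this difference with limma. IAPEz-int had a difference of 1.99 after centring (adjusted p = 0.305) and 1.83 with quantile normalisation (adjusted p = 0.255), and IAPLTR1_Mm of 2.08 (adjusted p = 0.235) and 1.95 (adjusted p = 0.200). Without both 2i libraries numbered 3 the differences of IAPEz-int and IAPLTR1_Mm were 2.11 and 2.07 and neither passed (adjusted p = 0.135 and 0.0711). Without all 4 libraries numbered 3 they were 2.46 and 2.32 and both passed (adjusted p = 0.00885 and 0.00439). These omissions were chosen after the data were examined. Without 1 library at a time no family passed without 2i control replicate 1, serum control replicate 1 or 3, or serum knockdown replicate 1 or 2. In turn 1 passed without 2i control replicate 3, 2i knockdown replicate 2 or 3 or serum control replicate 2. Of 14487 genes 0 passed with limma, 404 had an unadjusted p under 0.05, and voom on the recovered reads called 0. Gm5662 had a difference of 4.34, Lum of 3.36, Tex101 of 2.92, Rtp4 of 2.47 and Cthrc1 of −2.69, with adjusted p values of at least 0.94. In simulated data 8-fold differences were called for 39.4% of changed genes, so smaller ones were mostly not detectable. Without 2i knockdown replicate 2 the count of genes was 1, Lum.

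**Figure D3:**
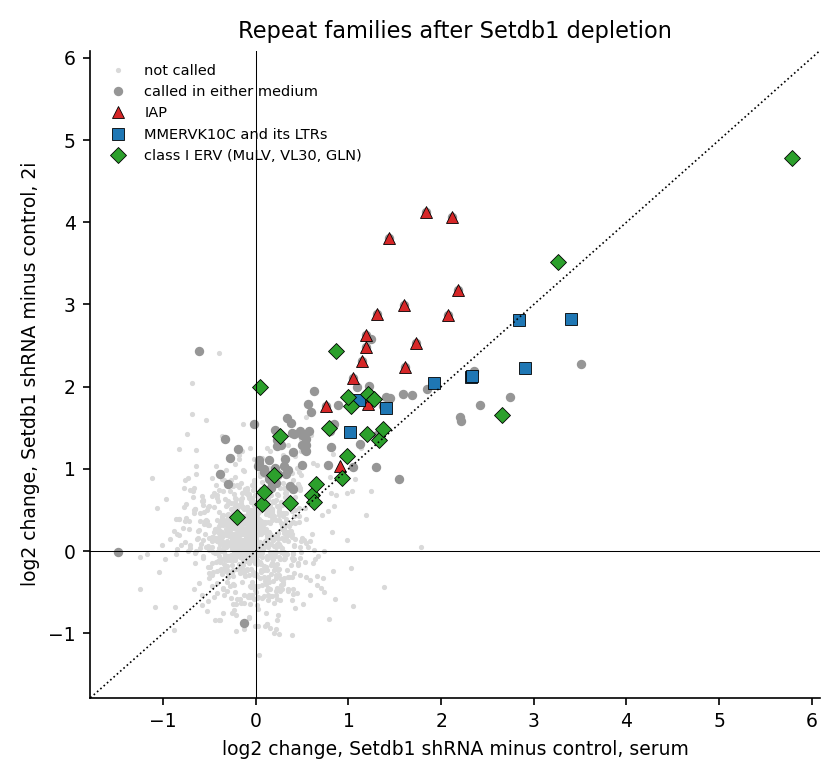
Log2 change of each tested repeat family after Setdb1 knockdown in serum (horizontal) and in 2i (vertical), with families called in either medium and members of chosen lists marked and a dotted line where both changes are equal. IAP families lie above the dotted line, with medians of 1.37 in serum and 2.58 in 2i under the deposited scaling and higher in 2i under every scaling, while MMERVK10C families have medians of 2.32 and 2.12, an order that reverses with the size factors of the gene table.

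The fourth comparison set 2i against serum in control cells. Genes of the 2-cell stage were lower in 2i: 17 of 25 fell, 23 when adjusted over the list alone, with a median of −2.71 (camera adjusted p = 1.08e-23, adjusted p = 0.397 with an estimated correlation). Zscan4c, a zinc finger gene of that stage, had 1940 ± 1651 reads in serum and 14.1 ± 18.2 in 2i (SD, n = 3), a log2 change of −5.33. Zscan4f (−5.50), Zscan4d (−5.02), Zscan4b (−4.95), Zscan4e (−4.78), Zscan4-ps2 (−5.45) and Gm5662 (−5.50) also fell, although reads of these near-identical copies are uncertain. With voom the 6 Zscan4 copies did not pass, with log2 changes of −9.17 to −7.38 and adjusted p values of 0.0591 to 0.108, while Gm5662 did. The fold of Zscan4c was 138 with all libraries, 70.8 without serum control replicate 2, 91.8 without 2i control replicate 3 and 512 without 2i control replicate 1. Wnt response genes had 3 of 15 higher, with 3 higher and 2 lower when adjusted over the list alone, and a median of 0.37 (camera adjusted p = 0.0215, adjusted p = 0.522 with an estimated correlation). The feedback inhibitor Axin2 rose 7.41-fold from 100 ± 29.3 to 743 ± 15.9 reads, the transcription factor Sp5 55.7-fold and T, a mesoderm regulator, 36.3-fold, and both of the latter had no read in serum without serum control replicate 2.

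MEK-ERK response genes had 0 higher and 3 of 19 lower, with 1 and 8 when adjusted over the list alone, and a median of −0.89 (camera adjusted p = 4.84e-05, adjusted p = 0.397 with an estimated correlation). The ERK antagonist Spry4 had 762 ± 448 reads in serum and 18.8 ± 10.2 in 2i, the phosphatase Dusp5 changed by −1.49 and the ETS factor Etv4 by −1.74. Cholesterol synthesis genes were positive in 23 of 23, with 1 passing, the squalene synthase Fdft1 (1.10, 2.17-fold), and 4 when adjusted over the list alone. Their median was 0.61 (camera adjusted p = 1.97e-06, adjusted p = 0.397 with an estimated correlation). General pluripotency genes had 4 of 20 lower, the same number adjusted over the list alone, and a median of −0.63 (camera adjusted p = 0.00161, adjusted p = 0.397 with an estimated correlation). They were the Ras-family gene Eras, at 703 ± 107 and 13.9 ± 9.18 reads, Dppa2 (−2.50), Tcf15 (−1.82) and Dppa4 (−1.48). Naive pluripotency genes had a median of 0.25 with 0 of 20 passing (camera adjusted p = 0.0782), with Tcl1 at 1.38 (adjusted p = 0.0846). Primed genes had 2 of 18 higher and 2 lower, 2 and 3 when adjusted over the list alone, with a median of −0.50 (camera adjusted p = 0.142). The signalling antagonists Lefty2 (2.32) and Fst (2.04) were higher and the DNA methyltransferase Dnmt3a (−2.23) and Etv4 lower.

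Germline genes had 4 of 36 lower, 6 when adjusted over the list alone, and a median of −0.29 (camera adjusted p = 0.0361, adjusted p = 0.647 with an estimated correlation). They were Mael (−3.37), the helicase Ddx4 (−2.20), Gm1564 (−1.65) and Tdrd1 (−1.44). Interferon response genes had 3 of 27 higher, Xaf1 (2.04), the MHC light chain B2m (1.73) and Oas1a (1.71), and 5 when adjusted over the list alone. Their median was 0.21 (camera adjusted p = 0.0236, adjusted p = 0.397 with an estimated correlation). The p53 target list had 2 of 30 lower, the apoptosis genes Pmaip1 (−3.47) and Perp (−2.31), and 1 higher and 4 lower when adjusted over the list alone. Its median was −0.24 (camera adjusted p = 0.0215, adjusted p = 0.442 with an estimated correlation). Endoderm genes had 2 of 16 lower and 3 when adjusted over the list alone. The receptor gene Cubn was at least 164-fold lower, at 0 reads in 2i, and the laminin Lamb1 stood at −2.25. The list median was −0.46 (camera adjusted p = 0.0240, adjusted p = 0.482 with an estimated correlation). Neural genes had 1 of 7 lower, Neurod1 (−2.80), 3 when adjusted over the list alone, and a median of −1.27 (camera adjusted p = 0.0312, adjusted p = 0.397 with an estimated correlation). Histone genes had a median of −0.62 with 0 of 32 passing (camera adjusted p = 0.00220, adjusted p = 0.647 with an estimated correlation). In the same controls structural RNA took 24.2 to 48.3% of repeat reads in serum and 32.1 to 64.6% in 2i.

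Of imprinted genes 1 of 38 was higher, Plagl1 (2.17), and 2 lower, the cell cycle inhibitor Cdkn1c (−3.44) and Phlda2 (−1.70), with 1 and 4 adjusted over the list alone (median −0.28, camera adjusted p = 0.0782). Of DNA methylation genes 2 of 17 were lower, Dnmt3a and Gadd45a (−1.54), 4 when adjusted over the list alone (median −0.31, camera adjusted p = 0.0511). Of mesoderm genes T was higher and Mesp2 (−1.21) lower, 2 and 2 adjusted over the list alone (median −0.50, camera adjusted p = 0.710). Trophoblast, retroelement silencing, fibroblast, ribosomal protein and stress response lists had no member passing, with medians of −0.32, −0.15, −0.62, 0.04 and 0.01 and camera adjusted p between 0.120 and 0.901. Adjusted over the list alone the trophoblast and stress response lists each had 1 gene higher and 2 lower. The largest rises were the channel Trpm1 (52.2-fold, 79.2 ± 39.9 to 4130 ± 1987 reads), the homeobox genes Crxos1 (4.35) and Nkx1-2 (4.04) and Dmgdh of choline breakdown (3.58). Others were Jakmip1 (3.09), the desaturase Scd1 (3.07), the channel Aqp3 (3.02) and Calr4 (2.99). BB287469 (−4.32) and the endocytic receptor Lrp2 (−3.95) were among the largest falls.

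In all, 524 genes passed between the media with limma, 251 higher and 273 lower in 2i, and the groups did not overlap for 23.8% of genes, where chance gives 10%. Without 1 library at a time the count was 238 without 2i control replicate 2, 171 without 2i control replicate 3, 241 without serum control replicate 1 and 182 without serum control replicate 2. In every such fit 27 of the 49 genes taken by the naming rule kept their call. Among the others Lefty2 and Mesp2 lost it in all 6 fits. B2m, Dusp5, Etv4, Fdft1, Gm1564, Oas1a and Plagl1 lost it in 5. Aqp3, Dnmt3a, Dppa2, Dppa4, Gadd45a, Lamb1, Lrp2, Perp, Phlda2 and Spry4 lost it in fewer. Besides the Zscan4 copies, Aqp3, Dusp5, Lefty2, Oas1a, Plagl1, Sp5, Spry4, T and Tdrd1 did not pass with voom.

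Most repeat families had lower values in 2i control cells, with a median change of −0.52. MERVL-int had 106400 ± 24010 reads in serum and 4705 ± 2216 in 2i (log2 change −4.60, −4.08 relative to the shift, SE 0.66, limma adjusted p = 0.00349). Its long terminal repeat MT2_Mm changed by −3.53. In the MERVL and MT2 list 5 of 7 families fell, 6 when adjusted over the list alone, with a median of −1.07, or −0.55 relative to the shift (camera adjusted p = 0.0011, adjusted p = 0.766 with an estimated correlation). The other 3 were MT2C_Mm (−1.50), MERVL_2A-int (−1.07) and MT2B (−0.69), the last chosen after its values were seen. MaLR families had 37 of 103 lower, 50 when adjusted over the list alone, such as ORR1A3-int (−2.67) and ORR1D-int (−1.36), with a median of −0.73, relative −0.21 (camera adjusted p = 0.000282, adjusted p = 0.766 with an estimated correlation). Mouse L1 had 9 of 16 lower, 11 when adjusted over the list alone, such as L1Md_A (−2.02) and L1Md_F (−1.48), with a median of −1.15, relative −0.63 (camera adjusted p = 0.0105, adjusted p = 0.766 with an estimated correlation). These 3 medians stayed negative under every scaling tried.

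SINEs had a median of −0.63, relative −0.11, with 0 of 22 passing (camera adjusted p = 0.0283, adjusted p = 0.766 with an estimated correlation). IAP families had 1 of 16 higher, IAPEY_LTR (1.57), and 2 lower, IAPLTR4_I (−1.82) and IAPEY3-int (−0.99), 1 and 3 adjusted over the list alone. Their median was −0.32, or 0.20 relative to the shift, and turned positive after centring, with quantile normalisation and when scaled without structural RNA. Class I families had 1 of 24 higher, RLTR1B-int (1.87), and 6 lower, such as MuLV-int (−1.60), with 2 and 6 adjusted over the list alone (median −0.81, relative −0.29). Other class II families had 1 of 91 higher, RLTR13B2 (1.04), and 20 lower, such as RLTR20A2 (−1.34), 2 and 31 adjusted over the list alone (median −0.59, relative −0.07). Their median was 0.01 when scaled without structural RNA. MMERVK10C-int (−1.42) was the 1 of 9 of its list to fall, 0 adjusted over the list alone (median −0.48, relative 0.04). Camera placed the IAP and MMERVK10C lists above other families against the sign of their medians. Camera adjusted p for these 4 lists and for ETn and MusD (median −0.84, relative −0.32, 0 of 5 passing) lay between 0.0822 and 0.698. Structural RNA and tRNA repeats had a median of −0.19, relative 0.33, with 0 of 76 passing, and camera placed them above other families (adjusted p = 0.000237, adjusted p = 0.766 with an estimated correlation), although fry gave a downward direction. The satellite median was −0.76, relative −0.24.

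In all, 188 of 1097 families passed between the media with limma, 6 higher and 182 lower, and the groups did not overlap for 41.6% of families, where chance gives 10%. The split was 18 higher and 46 lower after centring, 18 and 16 with quantile normalisation and 26 and 15 when scaled without structural RNA. The count was 9 without 2i control replicate 1, 16 without 2i control replicate 3, 6 without serum control replicate 1 and 5 without serum control replicate 3. In every such fit 4 of the 30 named families kept their call, MERVL-int, MT2_Mm, MT2C_Mm and ORR1A3-int. With voom IAPEY3-int, IAPEY_LTR and IAPLTR4_I did not pass.

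**Figure D4:**
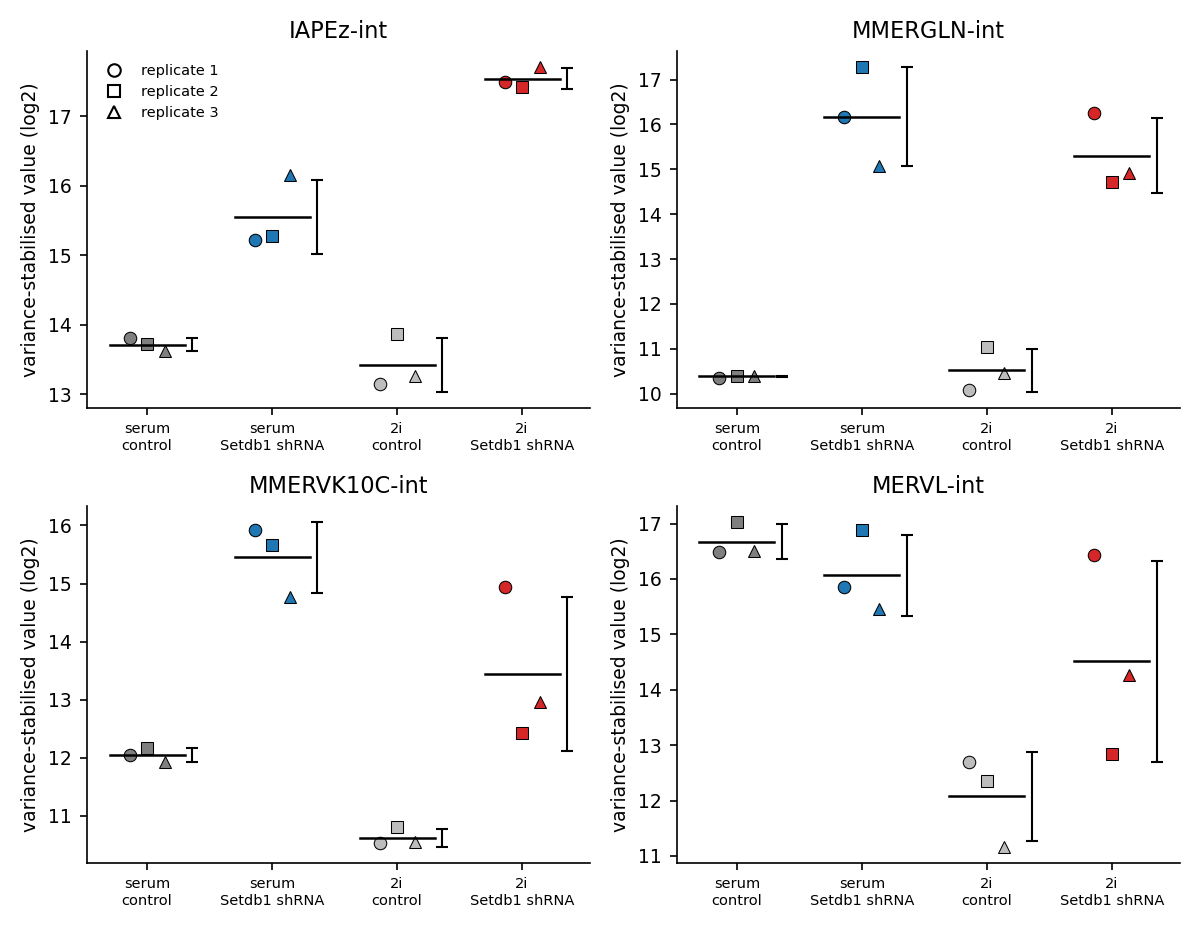
Deposited variance-stabilised values (log2) of 4 repeat families in each of the 12 libraries, with a marker shape for each replicate number, a line at the group mean and an error bar of 1 SD. IAPEz-int is higher after knockdown in both media and under every scaling, and MERVL-int is lower in the 2i controls than in the serum controls under every scaling.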

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

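The difference between the knockdown responses of the media was set before the data were examined, while the tests of explanations in this part were all chosen after the result was seen. Endogenous retroviruses of the IAP group stood out. IAPEz-int rose by 2.28 more and IAPLTR1_Mm by 2.38 more in 2i than in serum on the log2 scale. The IAP list had a median difference of 1.11, positive for 16 of 16 families (camera adjusted p = 6.86e-07, adjusted p = 0.109 with an estimated correlation, fry adjusted p = 0.00821). Both family calls were lost after centring, quantile normalisation and scaling without structural RNA, where the differences were somewhat smaller and their standard errors somewhat larger. For IAPEz-int they were 1.99 (SE 0.45), 1.83 (SE 0.46) and 1.96 (SE 0.46) against 2.28 (SE 0.44). For IAPLTR1_Mm they were 2.08 (SE 0.42), 1.95 (SE 0.38) and 2.07 (SE 0.44) against 2.38 (SE 0.38). Of 100 splits of the libraries within each medium, the real one included, 7 called at least the 2 families called here and the highest other called 87. Splits that swap all labels of 1 medium add both knockdown effects, so this comparison cannot decide. Chance stays open for the count of families.

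The tables bear on 3 simple explanations of the larger IAP rise and argue against the first and the last. A scaling artefact would move the other families alike, but relative to the median of the other families the IAP mean still rose by 0.92 more in 2i (SE 0.31). A deeper knockdown would raise other targets in step, and relative to the MMERVK10C list the IAP mean rose by 1.23 more (SE 0.40). That list was chosen after its own mean difference of −0.01 was seen. The means were 0.11 for ETn and MusD, 0.39 for other class II and 0.41 for class I families. The comparison therefore cannot decide on a deeper knockdown. The fall of Setdb1 itself was smaller by 0.09 in 2i (−2.24) than in serum (−2.33), a difference that did not pass. A lower starting level would leave the end levels alike, but relative to the median of the other families the IAP mean of the 2i knockdown exceeded that of the serum knockdown by 0.98 (SE 0.22), while on the same relative scale the controls differed by 0.06. A larger dependence of IAP families on SETDB1 in 2i may account for the pattern, as a hypothesis found and examined on the same libraries. Changes in other silencing pathways in 2i stay open as well. In 2i against serum controls the retroelement silencing list had a median of −0.15 with 0 of 38 passing. The DNA methylation list had a median of −0.31 with 2 of 17 lower, among them Dnmt3a (−2.23). Whether these RNA levels bear on the IAP rise was not tested.

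Other repeat lists differed between the responses by camera. The median difference was 0.40 for other class II families (adjusted p = 0.0133), 0.66 for MERVL and MT2 (adjusted p = 0.0108) and 0.45 for MaLR (adjusted p = 0.00218). It was 0.78 for mouse L1 (adjusted p = 0.0117) and 0.88 for structural RNA and tRNA repeats (adjusted p = 0.00144). Relative to the shift of all families of 0.31 these were 0.09, 0.35, 0.14, 0.47 and 0.57. Each had an adjusted p = 0.738 with an estimated correlation.

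Among gene lists, the difference was 1.54 for genes of the 2-cell stage (camera adjusted p = 9.77e-13), positive for 22 of 25 members. It was −0.73 for primed and early post-implantation genes (adjusted p = 0.000365), negative for most of 18, and 0.41 for naive pluripotency genes (adjusted p = 0.0417). It was 0.34 for interferon response genes (adjusted p = 0.0056), −0.41 for cholesterol synthesis genes (adjusted p = 0.000365), 0.71 for histone genes (adjusted p = 2.14e-05) and 0.59 for ribosomal protein genes (adjusted p = 6.60e-05). The histone and ribosomal protein lists also differed by 0.95 and 1.32 between the 2i libraries rich and poor in structural RNA. The primed, cholesterol synthesis and interferon lists differed by −0.51, −0.18 and 0.09 there, the same way as their differences here. The 2-cell-stage and naive lists went the other way, by −0.38 and −0.27. As 2 of the 3 rich libraries were of the knockdown, composition stays open for the lists that moved the same way. With an estimated correlation the adjusted p of the lists named here ranged from 0.484 to 0.808, and no member passed over all genes with limma, where 404 of all genes had an unadjusted p under 0.05 and voom called 0.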

How the results depend on the processing

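Voom, array weights, gene-table factors, scaling without structural RNA, the structural RNA covariate and fits without libraries numbered 3 were chosen after the data were examined. Setdb1 kept its fall in both media throughout, while its difference between the media, which never passed, ranged from −0.183 to 0.418 over the omissions of 1 library and was negative without serum control replicate 1 (−0.124), 2i control replicate 3 (−0.067) or 2i knockdown replicate 1 (−0.183). Of 3569 values of the 180 named passing results under alternatives, 2903 kept their side of the threshold, 666 lost it and 0 changed sign. Alternatives that change only the filter, the spread or the block leave the change itself as it was in this balanced design. The 0 was therefore partly fixed in advance. Where no reason is given, the cause was not tested. After thinning all libraries to the 4821181 gene reads of 2i knockdown replicate 3, the shallowest, 167 genes were called in 2i instead of 184.

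With the replicate number as a block over all libraries or within medium, the serum gene count of 94 became 171 and 211, that of 184 in 2i 321 and 425, and the overlap of 60 became 98 and 121. Serum repeats of 37 became 63 and 72, 2i repeats of 115 became 153 and 168, and the repeat difference of 2 became 6 and 21. For that difference IAPEz-int (limma adjusted p = 0.00397 and 9.69e-06) and IAPLTR1_Mm (limma adjusted p = 0.00148 and 2.84e-07) passed in both blocked fits. So did MERVL-int in 2i (limma adjusted p = 0.00181 and 1.8e-12). The gene difference of 0 became 2 within medium, Gm5662 and Gm2016, the latter chosen after its value was seen. Between the media 1351 genes passed over all libraries instead of 524. Same-numbered libraries correlated at 0.46, 0.06 and 0.52 in 2i and at 0.23, −0.18 and 0.22 between the control groups. For repeats the values were 0.21, 0.04 and 0.24 in serum, 0.40, −0.02 and 0.46 in 2i and 0.09, −0.11 and 0.18 between the control groups. In serum every library correlated best with its own number in both tables, although weakly for repeats, and in 2i replicates 1 and 3 did but replicate 2 did not, so the numbers did not pair all libraries there. Libraries numbered 3 had the highest share of structural RNA in each group. The block kept all 51 list calls of 124 tests and added 3. With an estimated correlation 5 list calls held and with fry 16.

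With array weights, which did not fully converge in some fits, the counts were 272 (serum genes), 837 (2i genes), 1 (gene difference, Cthrc1), 1340 (genes between media), 61 (serum repeats), 438 (repeats between media) and 139 (overlap). With the structural RNA covariate they were 222, 376, 1198 (genes in serum, in 2i and between media), 191 and 13 (repeats in 2i and their difference) and 125 (overlap). Without the 4 libraries numbered 3 they were 54 and 89 (genes), 5 and 15 (repeat difference and between media) and 37 (overlap), and without both such 2i libraries 68 (2i genes), 0 (repeat difference) and 38 (overlap), with fewer samples in each fit. With only the 2 groups compared they were 88 (2i genes) and 75 (2i repeats), with fewer samples to estimate the spread. Serum repeats rose to 66 in that fit, and the cause was not tested. Voom called 114 genes in 2i. With gene-table factors 337 families passed in 2i and 376 between media. The repeat difference was 1 with no filter and 0 after centring, with quantile normalisation, without a trend and scaled without structural RNA. Repeats between media were 64 centred, 34 with quantile normalisation, 116 without a trend, 101 with a minimum log2 change of 1, which only removes smaller changes, and 41 without structural RNA.

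Omitting 1 library gave 37 to 69 serum genes, 99 to 253 2i genes, 0 to 1 for the gene difference and 171 to 466 genes between media. It gave 26 to 37 serum repeats, 71 to 120 2i repeats, 0 to 2 for the repeat difference, 5 to 250 repeats between media and 30 to 55 for the overlap.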

Other observations

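In this part the tests of gene neighbourhoods, chromosomes, structural RNA per gene read, composition and depth were set before their results were seen, and those of name families, scaling, sample labels and splits after. Some genes that rose after Setdb1 depletion lay close to each other, here within 3 tested genes and not always adjacent. On chromosome 13 Asb13 rose in 2i near Akr1c18, an aldo-keto reductase that inactivates progesterone (2.91, limma adjusted p = 0.0106). On chromosome 6 Ccdc126 (1.54, adjusted p = 0.0168) rose in serum with Stk31 near it on one side and Igf2bp3, an RNA-binding protein of development (1.30, adjusted p = 0.0413), on the other. Klrb1a, a natural killer cell receptor (2.04, adjusted p = 0.0340), rose in 2i near Clec2i and Clec2h (1.89, adjusted p = 0.00443). Tex101 and Ceacam10 (2.47, adjusted p = 0.0238) lie near each other on chromosome 7 and rose in 2i. These genes were chosen after their values were seen.

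Of 204 genes called higher in either medium, 190 had a place in the gene order of the GRCm38 assembly (93.1%). Of these, 30 had another such gene of another name family within 3 tested genes, against a median of 10 and a highest value of 28 in 1000 random gene sets. Local loss of repression that reaches more than 1 gene is a candidate explanation for the 30, and reads running from 1 gene into the next, overlapping genes and related genes with unlike names, such as Ifi204 and Mndal, stay open. By name, 4 of 952 families held more risen genes than chance gives in Fisher's exact test for an excess. They were Akr (4 of 12, adjusted p = 0.0128), Serpina (3 of 5, adjusted p = 0.0128), Cyp (5 of 31, adjusted p = 0.0211) and Clec (3 of 7, adjusted p = 0.0220). The acyl-CoA thioesterase family Acot had 3 of 11 (adjusted p = 0.0795). Shared reads among close copies may contribute to the 4 families and were not tested. The filter on the mean over all 12 libraries kept a gene silent in all controls only where knockdown libraries held its reads. It can thus lift the share of risen genes in a family, and the p-values do not allow for it.

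Of tested genes with a place in that gene order, 6 of 12 on chromosome Y rose in either medium, or 50%, against 1.28% of 13472 autosomal genes (Fisher's exact test, odds ratio 76.9, adjusted p = 8.71e-09). They were Ube1y1, Usp9y, Gm4064, Gm10256, Gm10352 and Gm3376, several of them near-identical copies that may be counted from the same reads, so fewer than 6 separate genes could lie behind the 8.71e-09. Rbmy1a1, whose symbol matches more than 1 gene of that assembly, had no such place and is not among the 12. A gene was tested by its mean over all 12 libraries, the knockdown included. One silent in all controls was therefore tested only where knockdown libraries held its reads, which can by itself lift the share that rose. The odds ratio and the 8.71e-09 thus do not show alone that chromosome Y responded more. On chromosome X 11 of 554 rose, 1.99% (Fisher's exact test, p = 0.177).

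Most repeat families had lower values in the 2i controls than in the serum controls. With the size factors of the gene table the median family still differed by −0.56 (SE 0.17), against −0.41 (SE 0.14) with those of the repeat table, which argues against the scaling of the repeat table as the whole cause. Repeat reads outside structural RNA, per gene read, differed by −0.86 on the log2 scale (SE 0.19), which argues against a larger share of structural RNA as the whole cause. When the repeat table was scaled without structural RNA the called families went from 6 higher and 182 lower to 26 and 15, and factors taken from the other families remove by construction any shift that these share. The amount of unspliced or nuclear RNA in the libraries stays open, as does an effect of the medium.

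A split of the 2i libraries that ignores the knockdown, with control replicate 3 and knockdown replicates 2 and 3 on one side, called 623 genes, 399 higher and 224 lower on that side, of which 1 was also called by the knockdown. Of these genes 88% differed the same way between serum libraries numbered 3 and the other serum libraries, against 66% of genes not called, consistent with library composition as a candidate source. Whether the extraction kit differed between libraries is not clear from the labels. Depth as the whole cause is argued against by 573 genes called after thinning all libraries to the depth of the shallowest, where the knockdown called 167. Exchanged labels are argued against by Setdb1 and IAPEz-int, which placed 3 of 3 knockdown libraries apart from all controls. That split raised ribosomal protein genes, with a median of 1.32 and 29 of 49 passing.

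With 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real and the highest other count were 94 and 0 for serum genes, 37 and 0 for serum repeats, 184 and 623 for 2i genes, 115 and 3 for 2i repeats, 524 and 0 for genes and 188 and 0 for repeats between the media. For lists they were 12 and 19 in serum, 10 and 15 in 2i and 16 and 13 between the media, and 5, 7 and 1 of the 10 splits gave as many. For serum genes, 4 splits part all 3 same-numbered pairs, and the other 3 called at most 0. For the gene difference between the knockdowns, where 0 genes passed with limma, 404 had an unadjusted p under 0.05 and voom called 0, the comparison with 100 splits was void, since any count reaches 0. The highest other count was 2339.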
